A study of Mus musculus with 16 samples.

How the data were processed

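Gene expression was measured on 16 Affymetrix mouse GeneChip arrays, 1 per sample. Per the labels' protocols, OT-I CD8 T cells from wild-type donors (WT) or from donors lacking TRAF6 (KO) were moved into congenic recipients. The recipients were infected with an attenuated Listeria monocytogenes strain that carries Ova. Blood and spleen of single mice were taken at day 6 or day 10, and donor cells were sorted on CD45.2. RNA was amplified with a NuGEN Ovation kit before labelling, also per the labels' protocols. There were 3 arrays per genotype at day 6 and 5 at day 10, and each array was taken as 1 mouse. The part of Traf6 that is deleted, and the sex of donors and recipients, are not given in the sources used here.

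The deposited table holds log2 expression values for 45101 probe sets on the 16 arrays. Per the submitters' processing notes the values were made by the authors with GCRMA, a method that corrects for background and summarises the probes of a probe set. Its version and settings are not given in the sources used here. Every one of the value columns matched a sample, so 0 columns were left out. The range and floor of the values were checked and are those of a log2 scale, and no further transformation was applied. Of the probe sets, 64 are controls, 34945 carry 1 gene symbol, 932 carry several and 9160 others carry none. Only those with 1 symbol were used. A gene was measured by its probe set with the highest mean over all arrays, which gave 18193 genes. Genes with a log2 value over 4 in at least 3 arrays were tested, whatever the group of those arrays, which left 9390. Probe sets with several symbols or none, and control probe sets, stayed out of the tests.

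All 16 arrays entered 1 linear model with 4 group means in limma 3.58.1 (R 4.3.3), with its moderated test and Benjamini-Hochberg adjustment over the 9390 genes. The threshold was an adjusted p of 0.05. The 5 comparisons were KO minus WT at day 6, KO minus WT at day 10, day 10 minus day 6 in WT, day 10 minus day 6 in KO, and the interaction, which is the day 10 genotype difference minus the day 6 one. A positive interaction means a genotype difference that is more positive at day 10. All differences are on the log2 scale with the standard error (SE) of the model, and ± gives the standard deviation (SD) between arrays. Python 3.11.15 with pandas 2.3.3 prepared the tables and matplotlib 3.10.9 drew the figures.

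In each comparison 27 gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 27 lists. The lists hold 598 entries, of which 556 had a probe set. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction, stand beside it. The lists cover fatty acid oxidation, peroxisomal oxidation, fatty acid synthesis, sterol synthesis, lipid uptake and lipolysis, energy sensing and nuclear receptors, glycolysis, the citric acid cycle and oxidative phosphorylation. Lists of T cell state cover effector, memory and naive, inhibitory receptor and cell cycle genes. The inhibitory receptor list also holds transcription factor genes (Tox, Nfatc1, Nr4a1, Nr4a2, Nr4a3 and Ikzf2), so it is not a list of receptors alone. Lists of signalling cover the TRAF6 pathway, NF-kB targets, interferon response, TGF-beta, PI3K and mTOR, apoptosis, autophagy and lysosome, and immediate early and stress genes. Lists of markers of other cells cover B cells, myeloid cells, erythroid cells, platelets, CD4 and regulatory T cells, and NK cells. List genes without a probe set, among them Cpt1b, Acsl1 and Tcf7, were not analysed here. The mean of the fatty acid oxidation list was also compared per array with a two-sided exact permutation test, with a 95% interval from inverting the test.

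The lists, comparisons, filter, tests, most alternatives and the rule for naming genes were chosen before the data were examined. The rule names Traf6 on every probe set. In each comparison it names up to 10 genes per direction with the largest changes past the threshold and no overlap between the groups. Directions with fewer than 5 such genes are filled up to 5 by unadjusted p, and these are described as not past the threshold. The interaction names 5 genes per direction. Clone-like symbols are counted and not named. Each described list names up to 4 members of smallest unadjusted p. All 27 lists were tested in all 5 comparisons, but which lists below the threshold are described beside those past it was chosen after the list results were seen.

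For each array the share of probe sets over log2 4 and the 3′ minus 5′ difference of the beta-actin and Gapdh control probe sets were computed. After the data were seen, the arrays were divided by their beta-actin difference. Array set 1 holds the 8 arrays above the mean of all arrays, and array set 2 the other 8. KO day 10 replicate 1, at 2.719, lay just above that mean. It fell between the highest array of set 2 (2.174) and the next of set 1 (3.588). Its 18S ribosomal RNA controls were nearer to those of set 2. The myeloid gene Adgre1 read 6.944 on it, against 2.2 to 2.24 on set 2. Results by array set carry this choice unless that array was left out. The sets hold 1 and 2 arrays per genotype at day 6, and 3 and 2 at day 10. The labels name no batch, so the sets are groups defined from the control probe sets.

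The labels number the samples of each group, so the numbers were checked as pairs, by the correlation of residuals across genes between arrays of like number. At day 6 the correlations of WT with KO were 0.724, 0.52 and 0.43, all over the minimum of 0.1 set for treating numbers as pairs. The value with the number as a block is given beside that comparison. Replicate 1 of both genotypes lies in array set 1 there, and replicates 2 and 3 in set 2. The sets alone can give such correlations, so these do not show that like numbers are pairs. For number 3 the KO array closest to the WT array had another number. At day 10 the correlation of WT with KO was -0.0426 for number 1, which includes KO day 10 replicate 1. It was 0.122, 0.408, 0.32 and 0.373 for the other numbers, all over the minimum of 0.1. Between days the correlations ran from -0.385 to -0.0104 in WT and from -0.221 to -0.0285 in KO. As not every value lay over the minimum, these comparisons were not paired.

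The alternatives were other filters, quantile normalization, centring of arrays, other variance models, a fit of only the groups compared, a replicate block, other ways to choose a gene's probe set, other thresholds and leaving out each array in turn. Alternatives added after the data were seen were the array set as a block, each array set alone, the mean of B cell, myeloid and erythroid list genes as a covariate, the beta-actin difference as a covariate, combinations of these with KO day 10 replicate 1 left out, and the genotype difference averaged over both days. The model was tested on simulated data with 9390 genes of which 200 were changed. With a change of log2 2, limma recovered 48.4% of them for KO minus WT at day 6, 65.1% at day 10, 52.3% for the days in WT and 54% for the days in KO. At log2 1 it recovered 6.85%, 18%, 13.6% and 11.6%, and of the genes called at day 6 9.87% were false. The simulated noise was normal and independent between genes and arrays, with no array sets, no array that stands apart and no floor. These shares hold for such noise and need not hold for the real arrays. The number of arrays limits the precision: the median width of a gene's 95% interval to either side was 1.07 at day 6, 0.827 at day 10 and 0.955 between days.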

Results

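The series compares antigen-specific CD8 T cells with and without TRAF6, an adaptor and ubiquitin ligase downstream of Toll-like, interleukin 1 and several TNF family receptors. OT-I cells, whose transgenic receptor recognises a peptide of ovalbumin, were profiled after infection with Listeria that carries this antigen. The day 6 groups hold 3 WT and 3 KO arrays and the day 10 groups 5 WT and 5 KO arrays, each from 1 mouse per the labels. The title of the series names CD8 T cell memory and fatty acid metabolism as its subject. Between 38.15% and 39.62% of probe sets lay over log2 4 on all arrays except KO day 10 replicate 1, which had 35.85%. Cd3e and Cd8a, parts of the T cell receptor complex and its co-receptor, lay between 13.73 and 14.61 on every array.

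Traf6 itself separated the genotypes on every array. The tested probe set read 8.34, 7.81 and 7.32 in the WT arrays of day 6 and 2.93, 2.17 and 2.17 in the KO arrays. At day 10 the WT arrays read 8.01, 8.37, 7.93, 6.93 and 7.95, and the KO arrays 2.33, 2.21, 2.87, 2.17 and 2.17. In KO cells Traf6 was lower by 42.2-fold at day 6 (log2 difference -5.40, SE 0.37, n = 3 and 3, limma adjusted p = 7.2e-06) and by 44.9-fold at day 10 (-5.49, SE 0.29, n = 5 and 5, adjusted p = 1.9e-07). The KO values sit at the floor of the arrays near 2.2, so the folds depend on that floor. The other 4 Traf6 probe sets stayed near the floor on most arrays of both genotypes and reached at most 5.09 in WT and 5.27 in KO.

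**Figure D1:**
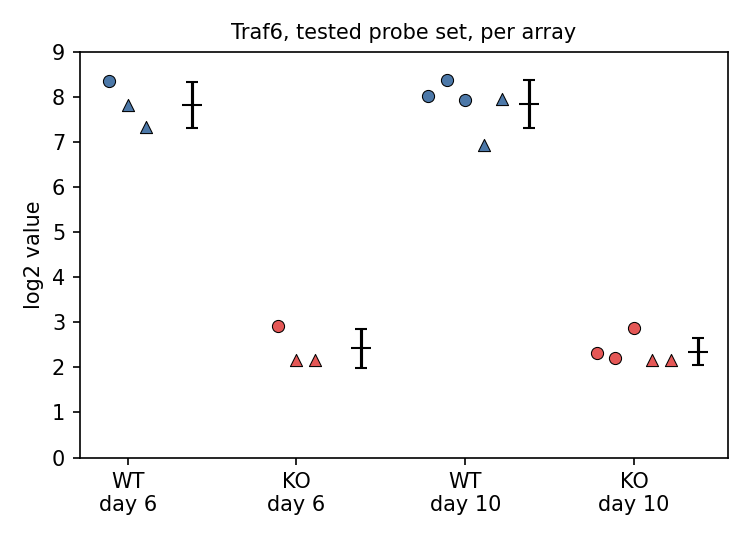
Log2 value of the tested Traf6 probe set on each of the 16 arrays by group. Blue marks are WT and red marks KO, circles are array set 1 and triangles array set 2 (divided by the beta-actin 3′ minus 5′ difference), and the black bar is the group mean with its SD. All WT arrays lie at 6.93 or above and all KO arrays at 2.93 or below.

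The genotype comparison at day 6 asks how loss of TRAF6 alters the cells near the peak of the response. Traf6 was the only gene past the threshold, and the genes of smallest p behind it did not pass. Ctla4, an inhibitory receptor, averaged 9.73 ± 0.46 (SD, n = 3) in KO and 8.22 ± 0.34 (n = 3) in WT cells. Ikzf2, which encodes the transcription factor Helios, averaged 7.58 ± 0.39 in KO and 3.80 ± 1.0 in WT. The HMG-box factor gene Tox2 had a difference of 2.56 (SE 0.59), the kinetochore gene Knl1 0.86 and Rcl1 2.82. On the other side stood Slc15a2, a transporter of small peptides (10.63 ± 0.28 in KO, 12.83 ± 0.36 in WT), with Mettl16 at -1.09, Trim17 at -2.15 and the recombination gene Rad54b at -1.54. Each of these genes had an adjusted p of 1.0.

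Among the gene lists, the inhibitory receptor list was past the threshold upward in KO cells at day 6 (camera adjusted p = 0.0053, median difference 0.09, mean 0.32). Of its 13 tested genes 8 were positive and 5 negative, 0 passed over all genes, and 2 rose when adjusted over the list alone, Ctla4 and Ikzf2 (both 0.0059). Its other named members were Tox at 0.72 and Nr4a3 at -2.12, with adjusted p of 1.0. Of these named members only Ctla4 encodes an inhibitory receptor. With an estimated correlation the list had an adjusted p = 0.277, and with fry 0.954. The cell cycle list came next, with 30 of 39 genes positive and a median of 0.10 (adjusted p = 0.0716). The fatty acid oxidation list, 10 of 21 genes positive, had a median of -0.01 (adjusted p = 0.940). Its members Eci1 at -0.43, Acads at -0.28, Hadhb at 0.19 and Acaa2 at -0.23 did not pass. The TRAF6 pathway list had 9 of 19 genes positive (adjusted p = 0.940). In it Irak2 stood at -0.78, Rnf31 at -0.56, Cyld at -0.11 and Tollip at 0.20. Median and mean of both these lists were slightly negative while camera ranked them upward against other genes. Single arrays moved some of the gene values: without KO day 6 replicate 1 Nr4a3 was at -0.78, Irak2 at -0.29 and Rnf31 at 0.81, and without KO day 6 replicate 2 Tox was at 0.37 and Eci1 at -0.18. The 26 lists not past the threshold had adjusted p from 0.0716 to 0.940, and 0 lists passed with an estimated correlation or with fry.

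In all, limma called 1 gene of 9390 at day 6, and 90 genes had an unadjusted p under 0.05 where chance alone would give 470. A count so far below 470 shows p-values larger than chance would give. The spread in the model holds the difference between array sets, which had no term in it. It also holds KO day 10 replicate 1, which enters the variance of every comparison. Without that array the genes called between days in WT, a difference that does not use it, were 540 instead of 283. How much each raised the p-values at day 6 was not tested. The lack of calls thus does not show that the genotypes are alike. With the replicate number as a block 2 genes passed, Traf6 and Ikzf2 (log2 difference 3.78, adjusted p = 0.032). For Ikzf2 the KO and WT arrays of day 6 did not overlap, so any pairing of them gives the same direction. That block also takes up the difference between array sets, and like numbers were not shown to be pairs. Leaving out KO day 10 replicate 1 added Slc15a2 (adjusted p = 0.047) and Cyp17a1 (0.043), leaving out KO day 6 replicate 1 added Rad54b and Recql4 (0.0022 each), and leaving out KO day 10 replicate 2 added Clip4 (0.041). The inhibitory receptor call ended without WT day 6 replicate 1 (adjusted p = 0.343) and without KO day 6 replicates 1 (0.136), 2 (0.0787) or 3 (0.0624), and had adjusted p of 0.0853 on array set 1 and 0.513 on array set 2.

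At day 10, in the phase when the expanded population shrinks, Traf6 was again the only gene past the threshold. Tmod4, which encodes a tropomodulin that caps actin filaments, averaged 8.93 ± 0.63 in KO and 5.42 ± 1.09 in WT cells (n = 5 and 5, log2 difference 3.50, SE 0.57), with an adjusted p of 0.125. Spry2, a feedback inhibitor of receptor tyrosine kinase signalling, had a difference of 1.35, the interferon-inducible Ifitm1 1.30, Cd163l1 1.54 and Spats2 1.18. Lower in KO without passing were Slc15a2 (11.23 ± 0.94 against 12.93 ± 0.34), the muscle-type glycogen synthase gene Gys1 (-1.63, adjusted p = 0.395), Acot6 at -1.82 and Pecam1 at -2.01. Apart from Tmod4 and Gys1 the adjusted p of these genes was 0.918. Over all tested genes the median difference was -0.16, which became -0.05 after quantile normalization and 0.04 after centring of the arrays, and single differences are to be read against it.

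Against that background camera placed 2 lists upward in KO cells at day 10. The effector list had a median of 0.06 and a mean of 0.02 over 27 genes, 15 of them positive (adjusted p = 0.0193, and adjusted p = 0.831 with an estimated correlation). KO day 10 replicate 1 lowers that mean difference. Its list mean was 10.60, against 11.46 to 12.16 on the other KO arrays and 11.19 to 11.91 on the WT arrays. Zeb2, a transcription factor of terminal effector cells, stood at 0.55 (SE 0.23), the effector marker Klrg1 at 0.31, Klrc1 at 0.17 and the granzyme gene Gzmk at -0.23. The immediate early and stress list had a median of 0.09 and 13 of 19 genes positive (adjusted p = 0.0296, and 0.395 with an estimated correlation), with Fos at 1.90, Jun at -0.55, Btg2 at 0.16 and Hsp90aa1 at 0.13. Without KO day 10 replicate 1 Fos was at 1.16, and without WT day 10 replicate 2 Jun was at -0.31 and Klrg1 at 0.15. In both lists 0 members passed, over all genes or adjusted over the list alone, and fry gave adjusted p of 0.878 and 0.564. Without a filter on low values the 2 lists had adjusted p of 0.0736 and 0.331.

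No list on the lower side in KO cells at day 10 passed with all arrays, no block, the deposited values and the filter on low values, tested by camera with its preset correlation. Interferon response and myeloid markers passed downward without a filter (adjusted p = 7.5e-05 and 0.00483), after quantile normalization (0.0413 and 0.0341), with the replicate number as a block (0.0139 and 0.00958) and with the array set as a block, which was chosen after the data were seen (0.00955 and 0.00543, with erythroid markers at 0.0464). With the beta-actin difference as a covariate 0 lists passed, and with an estimated correlation all 3 had an adjusted p of 0.831. The interferon response list had 24 of 25 genes negative and a median of -0.45 (adjusted p = 0.0516), with Rsad2 at -1.71, Oas3 at -1.70, Irf9 at -0.85 and Rtp4 at -0.76. Markers of myeloid cells were negative in 17 of 19 genes, with a median of -0.72 (adjusted p = 0.0797), among them the neutrophil genes Ngp at -3.16, S100a9 at -2.11 and Camp at -2.01, and Ctss at -0.40. Erythroid markers were negative in 8 of 8 genes (median -0.94, adjusted p = 0.140). Oxidative phosphorylation genes were negative in 28 of 30 (median -0.34, adjusted p = 0.0797). Their mean was 11.23 on KO day 10 replicate 1. The other KO arrays, at 12.87 to 13.21, lay inside the range of the WT arrays, 12.83 to 13.22. The lower mean in KO thus rests on that array. In the memory and naive list, 14 of 22 genes were negative (adjusted p = 0.751), with the homing receptor gene Ccr7 at -1.84, Slamf6 at -0.51, Dapl1 at -1.64 and Myb at -0.73. The TRAF6 pathway list, with 16 of 19 negative (adjusted p = 0.733), included Irak2 at -1.10, Myd88 at -1.23, Sqstm1 at -1.23 and Traf1 at -0.21. The fatty acid oxidation list had 17 of 21 genes negative, a median of -0.13 and a mean of -0.37 (adjusted p = 0.547), with Eci2 at -0.47, Acadl at -0.26, Acadvl at -1.58 and Acaa2 at -0.47. Many of these values rest on KO day 10 replicate 1: without it Myd88 was at -0.12, Sqstm1 at -0.13, Acadvl at -0.21, Acaa2 at -0.11, Oas3 at -0.67, Irf9 at -0.24, Rsad2 at -1.13, Rtp4 at -0.47 and Ctss at -0.25. Irak2 was at -0.68 without WT day 10 replicate 4 and Myb at -0.44 without KO day 10 replicate 5. Adjusted p of the 25 lists not past the threshold ran from 0.0516 to 0.916.

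The limma count at day 10 was 1 gene, with 238 genes under an unadjusted p of 0.05 where chance would give 470. As at day 6, so low a count means that the lack of calls does not show like genotypes. Single arrays changed the calls: Tmod4 passed without WT day 10 replicate 5 (adjusted p = 0.026, with Gys1 at 0.030) or WT day 6 replicate 1 (0.020), Slc15a2 without KO day 10 replicate 1 (0.017), Kdm4d without WT day 10 replicate 4 (0.025) and Eppk1 without KO day 10 replicate 3 (0.043). The effector call ended without KO day 10 replicates 4 (adjusted p = 0.156) or 5 (0.492) or WT day 10 replicates 2 (0.202) or 3 (0.0745), and had 0.213 on array set 1 and 1.2e-04 on array set 2. The immediate early call ended without KO day 10 replicates 4 (0.0834) or 5 (0.221) or WT day 10 replicates 1 (0.113), 2 (0.106) or 3 (0.0745), and had 0.03 on array set 1 and 0.299 on array set 2. Without KO day 10 replicate 1 the myeloid markers (median -1.26, adjusted p = 9.7e-04) and the interferon response list (-0.24, 0.0273) passed downward, and without WT day 10 replicate 5 they did as well (0.0011 and 0.0223), as they did without WT day 10 replicate 4 (0.0384 and 0.0147) and without KO day 6 replicate 1 (0.0282 for each). With all arrays and an estimated correlation these 2 lists had an adjusted p of 0.831. The interferon list also passed without KO day 10 replicate 3 (0.0368), KO day 6 replicate 2 (0.0414), WT day 6 replicate 1 (0.0457) or WT day 6 replicate 2 (0.0462).

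Fatty acid oxidation, the pathway that the series title points to, was also compared as 1 mean per array over its 21 tested genes. At day 6 this mean was 11.17 ± 0.13 in KO and 11.19 ± 0.06 in WT cells (n = 3 and 3, difference -0.01, exact permutation p = 0.9, where 0.1 is the smallest possible). At day 10 it was 10.59 ± 0.78 in KO and 10.96 ± 0.09 in WT (n = 5 and 5, difference -0.37, exact permutation p = 0.349, 95% interval -1.03 to 0.09). KO day 10 replicate 1, the array with fewer probe sets over log2 4, read 9.20 and the other 4 KO arrays 10.83 to 11.08. Without it the KO mean was 10.94 ± 0.10 (n = 4), the difference -0.03, the exact permutation p 0.683 and the interval -0.17 to 0.12. From day 6 to day 10 the mean fell by 0.22 in WT cells (exact permutation p = 0.0179, the smallest that 3 against 5 arrays can give, interval -0.37 to -0.07), a call that ended without WT day 10 replicate 4 or 5 (exact permutation p = 0.0571 for each). In KO cells the difference was -0.58 (exact permutation p = 0.268, interval -2.11 to 0.50). Much of it rests on KO day 10 replicate 1, without which the KO mean was 10.94 at day 10, against 11.17 at day 6. With the array set as a block the difference in WT was -0.22 (p = 0.0417 by stratified exact permutation), in KO -0.49, and between genotypes at day 10 -0.37 (p = 0.3).

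**Figure D2:**
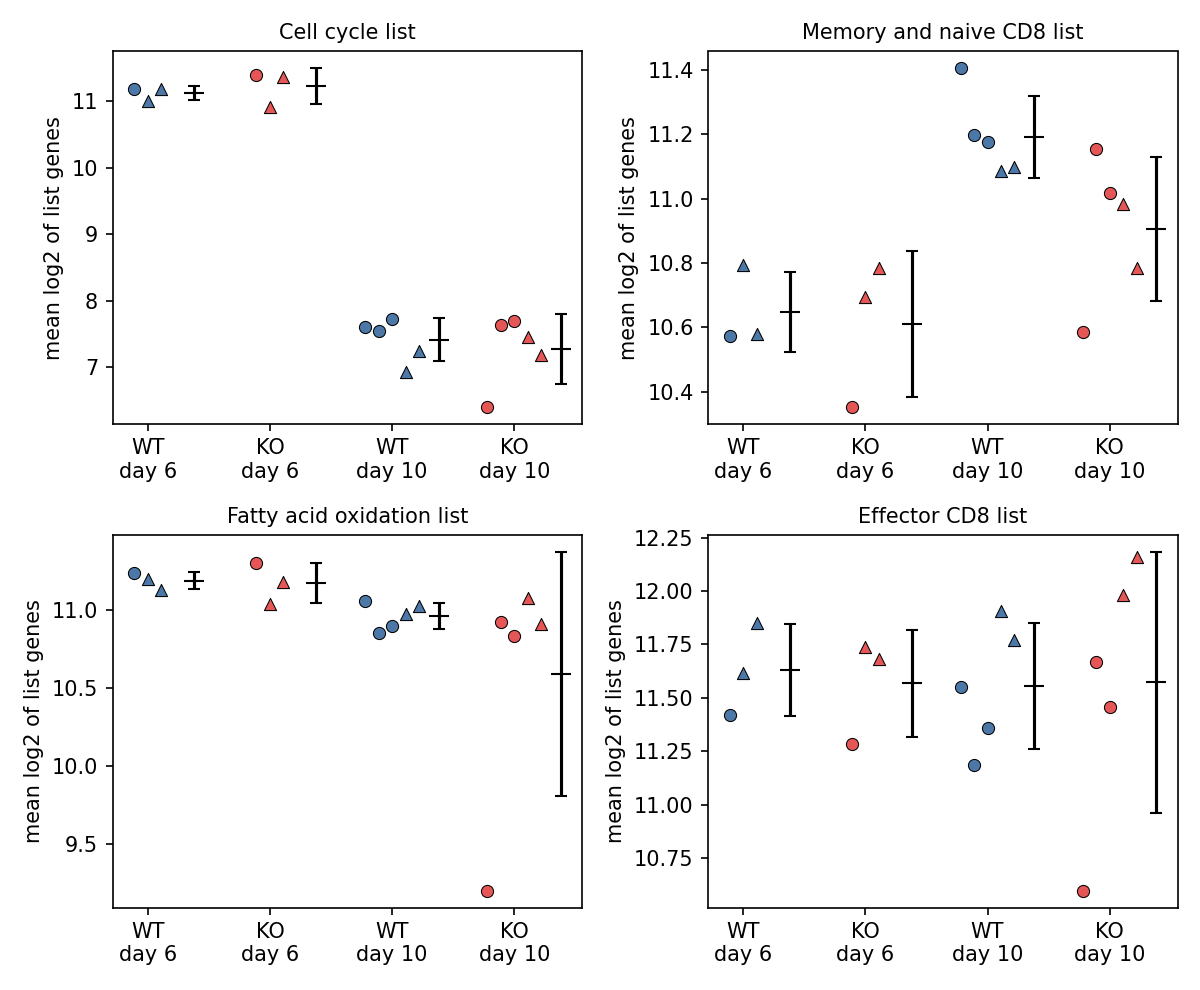
Mean log2 value over the tested genes of 4 lists on each array by group: cell cycle, memory and naive, fatty acid oxidation, and effector genes. Blue is WT and red KO, circles are array set 1 and triangles array set 2, and black bars give group mean and SD. Cell cycle means drop between the days in both genotypes, and KO day 10 replicate 1 lies lowest in the fatty acid oxidation panel at 9.20.

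The interaction asks whether loss of TRAF6 acts differently on the days. No gene passed: limma called 0 genes, with 84 under an unadjusted p of 0.05 and 470 expected by chance, and the smallest adjusted p was 0.9985. The count under an unadjusted p of 0.05 was 133 with the array set as a block and 131 without KO day 10 replicate 1. With both it was 206, still below 470. With counts so far below chance, the lack of calls does not show that TRAF6 acts alike on both days. The smallest unadjusted p toward a more negative KO difference at day 10 were those of Ctla4 at -2.08 (SE 0.44), the phosphate transporter gene Slc20a2 at -1.67, Tox2 at -2.54, the cation channel gene Mcoln2 at -2.63 and Gys1 at -1.70. In the other direction they were those of Mettl16 at 1.06, Rad54b at 1.44, Sumf1 at 0.89, the DNA helicase gene Recql4 at 1.56 and Bspry at 0.72. Camera called 0 of 27 lists, with adjusted p from 0.142 for the inhibitory receptor list to 0.896, and 0 passed with an estimated correlation or fry. The median interaction over all genes was -0.11. Without KO day 6 replicate 1 Rad54b and Recql4 passed (adjusted p = 0.035 for both), and lists passed without WT day 10 replicate 4 (5 lists), KO day 10 replicate 1 (2), WT day 6 replicate 3 (1) or WT day 10 replicate 5 (1).

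Transcripts of cell cycle genes fell between day 6 and day 10 in WT cells. Cdc6, which licenses replication origins, fell from 10.48 ± 0.17 (SD, n = 3) to 2.90 ± 0.38 (n = 5; log2 difference -7.59, SE 0.22, adjusted p = 7.2e-11). Values under log2 4 are near the floor of the arrays, so differences that start or end there depend on that floor. The spindle checkpoint kinase genes Bub1 (-8.51, adjusted p = 3.1e-06) and Bub1b (-7.47), the phosphatase gene Cdkn3 (-7.83), the kinetochore genes Nuf2 (-7.27) and Kntc1 (-7.00), the cohesin acetyltransferase gene Esco2 (-7.17), the spindle motor gene Kif11 (-7.12), the repressor E2f7 (-7.09) and Parpbp (-7.00) fell with it. In the cell cycle list 27 of 39 genes fell over all genes, 33 when adjusted over the list alone, and 38 had a negative difference (median -3.26, camera adjusted p = 2.3e-57, adjusted p = 4.8e-05 with an estimated correlation, fry 7.6e-09). The mitotic genes Birc5 (-5.16) and Aurkb (-5.83) were among them. Dmrta1, a DM-domain gene, rose from 2.48 ± 0.34, at the floor, to 9.11 ± 0.39 (log2 difference 6.63, SE 0.30, adjusted p = 3.1e-09). Further rises were those of Kcnj8, a subunit of ATP-sensitive potassium channels (4.74), the protease gene Prss12 (4.70), the clock gene Per3 (4.17), Cpne7 (4.09), Dtx4 (3.57), Sbsn (3.53), Vmn2r84 (3.24), the sulfate transporter gene Slc26a11 (3.09) and Parp8 (2.99). Leaving out single WT arrays of day 6 ended the calls of Prss12 (adjusted p up to 0.0691), Vmn2r84 (up to 0.102) and Slc26a11 (up to 0.106).

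In the memory and naive list 3 genes rose over the same days in WT cells. Il7r, the receptor for interleukin 7 that sustains memory cells, rose by 1.19 (SE 0.19, adjusted p = 0.0015), the survival gene Bcl2 by 1.91 (SE 0.31, adjusted p = 0.0019) and Bcl6, a repressor active in memory precursors, by 1.49 (SE 0.35, adjusted p = 0.030). Of the 22 genes in the memory and naive list 3 rose and 19 did not pass. Adjusted over the list alone 4 rose, Socs3 (1.58) being the fourth, and 18 of 22 were positive (median 0.28, adjusted p = 0.0133, adjusted p = 0.123 with an estimated correlation, fry 0.0025). Markers of other cells leaned the same way without passing as lists: B cell markers were positive in 11 of 11 genes (median 0.48, adjusted p = 0.245) and myeloid markers in 16 of 19 (median 0.38, adjusted p = 0.345), 1 of which rose past the threshold. CD4 and regulatory T cell markers (3 genes) had a median of 1.05 (adjusted p = 0.276). Among effector genes the chemokine gene Ccl4 rose by 1.59 (SE 0.29, adjusted p = 0.0056). Gzmk at -0.86 fell only when adjusted over the list alone (0.036), and Gzmb at -1.12 and Il2ra at -1.70 did not pass. The effector list had a positive median (0.06), a negative mean (-0.07) and a camera direction downward (adjusted p = 0.813). Havcr2, which encodes the inhibitory receptor TIM-3, fell from 9.76 ± 0.61 to 5.34 ± 0.85 (adjusted p = 0.0098) as the only called member of the inhibitory list (list adjusted p = 0.229). In that list Ctla4 stood at -0.94, Tox at 0.60 and Cd244a at -1.70. Without WT day 6 replicate 1 the call of Havcr2 ended (0.0656) and Cd244a was at -0.38. The call of Bcl6 ended without any 1 of the WT arrays of day 6 or without WT day 10 replicates 1, 2 or 3 (up to 0.130), and Socs3 passed without WT day 10 replicate 4 (0.0136).

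Of the 9 metabolic lists 3 passed downward in WT cells. Sterol synthesis was negative in 14 of 17 genes (median -0.48), the citric acid cycle in 20 of 22 (-0.17) and oxidative phosphorylation in 27 of 30 (-0.30), each with a camera adjusted p of 0.0192 and 0 members past, over all genes or over the list alone. With an estimated correlation the adjusted p were 0.425, 0.71 and 0.847, and with fry 0.193, 0.50 and 0.649. The sterol enzymes Sqle at -1.28, Cyp51 at -1.72, Idi1 at -2.54 and Pmvk at -0.74 had the smallest p of their list. In the citric acid cycle these were Idh3a at -0.73, Sdhc at -0.74, Idh2 at -0.73 and Fh1 at -0.50, and in oxidative phosphorylation Cycs at -0.50, Ndufa4 at -0.76, Uqcrfs1 at -0.74 and Cox5b at -0.31. Acadl, a mitochondrial acyl-CoA dehydrogenase, fell by 0.80 (SE 0.19, adjusted p = 0.038) as the only called member of the fatty acid oxidation list (16 of 21 negative, median -0.15, adjusted p = 0.0517), with Etfa at -0.72, Acsl4 at -0.33 and Acsl5 at -0.23. The call of Acadl ended without any 1 of the WT arrays except WT day 10 replicate 2 (adjusted p up to 0.162). Glycolysis genes did not pass as a list (adjusted p = 0.628), with Tpi1 at -0.63, Pdk1 at 1.33, Slc16a1 at -0.46 and Pgk1 at -0.28. The 22 lists not past the threshold had adjusted p from 0.0517 to 0.985.

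In WT cells 283 genes differed between the days by limma, 74 higher and 209 lower at day 10, and 268 of them by at least 2-fold. The count was 540 without KO day 10 replicate 1, 187 without WT day 6 replicate 1 and 188 without WT day 6 replicate 3, and it was 348 with the array set as a block, 215 on array set 1 and 244 on array set 2. It was 103 with the replicate number as a block, 615 in a fit of only the 2 groups and 2311 with array weights. Calls of lists ended without WT day 6 replicate 1 (citric acid cycle 0.127), WT day 6 replicate 2 (oxidative phosphorylation and sterol synthesis, 0.0569 each) or WT day 10 replicate 3 (oxidative phosphorylation 0.0651), while fatty acid oxidation passed without KO day 6 replicate 1 (0.0409), WT day 10 replicate 1 (0.0403) or WT day 6 replicate 3 (0.0454). Within array sets 1 and 2 the adjusted p were 5.4e-21 and 3.2e-40 for the cell cycle, 0.0112 and 0.0506 for memory and naive, 0.164 and 0.0112 for sterol synthesis, 0.037 and 0.0925 for the citric acid cycle, and 0.216 and 3.7e-04 for oxidative phosphorylation, which had 0.0753 with the set as a block.

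Transcripts of cell cycle genes also fell in KO cells between the days. Cdkn3 fell from 10.80 ± 0.68 (SD, n = 3) to 2.46 ± 0.13, at the floor (n = 5; log2 difference -8.34, SE 0.55, adjusted p = 1.7e-07), and Cdc6 had a difference of -7.47 (SE 0.22, adjusted p = 8.9e-11). Further falls were those of the centromere gene Cenpf (-7.85), Prr11 (-7.83), Esco2 (-7.51), Bub1 (-7.45), the checkpoint kinase gene Chek1 (-7.36), Bub1b (-7.34), the spindle assembly gene Tpx2 (-7.28) and the replication gene Mcm10 (-7.22). In the cell cycle list 30 of 39 genes fell over all genes and 38 when adjusted over the list alone (median -3.98, camera adjusted p = 2.7e-42, 2.4e-04 with an estimated correlation, fry 2.8e-09), Kif20a (-6.92) and Birc5 (-4.96) among them. The fall was not uniform: Kif11 read 9.703 and 9.615 on KO day 10 replicates 1 and 4, within the range of the KO arrays of day 6, and Kntc1 9.857 and 7.581 on replicates 1 and 5, while the WT arrays of day 10 read at most 3.906 and 4.616. Dmrta1 rose by 6.51 from the floor (SE 0.30, adjusted p = 3.5e-09). Also higher at day 10 were Kcnj8 (5.56), the kallikrein gene Klk13 (4.56), Prss12 (4.27), Dtx4 (4.01), Cpne7 (3.70), Eef1aknmt (3.50), the cilium gene Bbs2 (3.42), Camk2n1, an inhibitor of calmodulin kinase II (3.33), and the zinc finger gene Zbtb20 (3.20). Leaving out single KO arrays ended the calls of Klk13 (adjusted p up to 0.102), Prss12 (up to 0.0769), Eef1aknmt (up to 0.0673), Camk2n1 (0.0932, at 2.27 without KO day 6 replicate 2) and Zbtb20 (up to 0.219, at 2.09 without KO day 6 replicate 1).

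The memory genes Il7r (1.30, SE 0.19, adjusted p = 6.5e-04), Bcl2 (2.06, adjusted p = 9.0e-04) and Bcl6 (1.59, adjusted p = 0.016) rose in KO cells, and Socs3 stood at 1.48. Over all genes these 3 rose of 22 in the list, and adjusted over the list alone 6 rose and 1 fell. The list did not pass (median 0.15, adjusted p = 0.0503, adjusted p = 0.241 with an estimated correlation, fry 0.0155). The CD4 and regulatory T cell markers were positive in 3 of 3 genes (median 1.0, camera adjusted p = 0.197, fry 0.0383), with 1 past when adjusted over the list alone. The inhibitory receptor list, which also holds transcription factor genes such as Ikzf2, fell (median -0.56, 3 of 13 fell, adjusted p = 0.0221, adjusted p = 0.241 with an estimated correlation, fry 0.0101). Ctla4 (-3.02, SE 0.31, adjusted p = 2.4e-05), Havcr2 (-4.8, adjusted p = 0.0044) and Ikzf2 (-3.44, adjusted p = 0.024) fell, and Pdcd1, which encodes PD-1, stood at -2.63 (adjusted p = 0.162). Among effector genes Ccl4 rose by 1.61 (adjusted p = 0.0040) and Zeb2 by 1.02 (adjusted p = 0.039), Gzmk fell by 0.94 (adjusted p = 0.036), and S1pr5 stood at 1.48, with the list itself at an adjusted p of 0.583. Leaving out single KO arrays ended the calls of Bcl6 (adjusted p up to 0.0715), Ikzf2 (up to 0.0825), Gzmk (up to 0.101) and Zeb2 (up to 0.130), and Pdcd1 was at -1.63 without KO day 10 replicate 1.

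Of the 9 metabolic lists 4 passed downward in KO cells. Of the sterol synthesis genes 2 of 17 fell, Sqle by 1.91 (adjusted p = 0.0085) and Cyp51 by 2.21 (adjusted p = 0.045), and Idi1 stood at -3.19 and Sc5d at -2.29 (list median -0.51, adjusted p = 0.0221, 0.277 with an estimated correlation as adjusted p, fry 0.0282). In the fatty acid oxidation list Acadl fell by 1.02 (adjusted p = 0.0061), 2 of 21 genes fell when adjusted over the list alone and 18 were negative (median -0.45, adjusted p = 0.0221, adjusted p = 0.545 with an estimated correlation, fry 0.107). Etfa stood at -0.86, Eci2 at -0.81 and Eci1 at 0.63. The citric acid cycle (median -0.46, adjusted p = 0.0090, adjusted p = 0.545 with an estimated correlation, fry 0.0697) and oxidative phosphorylation (median -0.52, adjusted p = 0.0128, adjusted p = 0.925 with an estimated correlation, fry 0.436) passed downward with 0 members called. Dld at -2.21, Fh1 at -0.75, Pdha1 at -0.60 and Idh3a at -0.49 belong to the first, and Uqcrfs1 at -1.19, Ndufa4 at -0.88, Atp5pb at -0.76 and Cox5a at -0.52 to the second. KO day 10 replicate 1 had the lowest means of the day 10 KO arrays in both, 10.44 and 11.23, and the others read 11.43 to 11.68 and 12.87 to 13.21. The KO arrays of day 6 read 11.784 to 12.117 and 13.185 to 13.35. The size of both falls thus depends on KO day 10 replicate 1. Without it Uqcrfs1 (-0.70, adjusted p = 0.0391) and Idi1 (-3.97, 0.0254) passed, and Sc5d was at -1.17, Atp5pb at -0.39 and Cox5a at -0.27. The call of Sqle ended without KO day 6 replicate 1 (0.0516) and that of Cyp51 without any 1 of 6 KO arrays (up to 0.209).

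Lists that went up in KO cells between the days were the immediate early and stress genes (median 0.48, adjusted p = 0.0221, adjusted p = 0.241 with an estimated correlation, fry 0.0133) and the TGF-beta signalling genes (median 0.45, adjusted p = 0.0221, adjusted p = 0.241 with an estimated correlation, fry 0.0187). Of the first, Ier5 rose by 1.0 (adjusted p = 0.019), and Hspa1b stood at 5.08, Fosl2 at 0.81 and Egr2 at 1.56. Of the second 0 of 16 passed, with the inhibitory Smad7 at 0.83 (adjusted p = 0.074), Ski at 2.34, Smad3 at 0.61 and Smad4 at 0.45. Without KO day 6 replicate 1 Ski was at 0.43, Smad3 at 0.18 and Fosl2 at 0.42, and the call of Ier5 ended (0.70, adjusted p = 0.0848). The 19 lists not past the threshold had adjusted p from 0.0503 to 0.987.

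In KO cells 435 genes differed between the days by limma, 145 higher and 290 lower at day 10, and 397 of them by at least 2-fold. The count was 288 without KO day 6 replicate 1, 605 with the array set as a block, 871 on array set 1 and 294 on array set 2. It was 121 with the replicate number as a block, 143 in a fit of only the 2 groups and 737 with array weights. Without KO day 10 replicate 1 (621 genes) only the cell cycle and citric acid cycle (adjusted p = 0.0147) lists passed, with sterol synthesis and inhibitory receptors at 0.057, oxidative phosphorylation and TGF-beta at 0.0695, and fatty acid oxidation and immediate early genes at 0.0722. Fatty acid oxidation, TGF-beta and immediate early genes also ended without KO day 6 replicate 1 (0.0824 each), immediate early genes without KO day 10 replicate 5 (0.0508), inhibitory receptors without KO day 6 replicate 2 (0.0573) and sterol synthesis without KO day 6 replicate 3 (0.0687). Memory and naive genes passed without KO day 10 replicate 3 (0.0333), KO day 6 replicates 2 (0.0406) or 3 (0.0461), WT day 10 replicates 2 (0.049), 3 (0.0488) or 4 (0.045), or WT day 6 replicates 1 (0.0496) or 2 (0.0481). Within array sets 1 and 2 the adjusted p were 6.4e-15 and 3.2e-33 for the cell cycle, 0.0442 and 0.329 for fatty acid oxidation, 0.264 and 0.0081 for sterol synthesis, 0.137 and 0.0568 for inhibitory receptors, 0.0279 and 0.248 for TGF-beta, and 0.0779 and 0.019 for immediate early genes.

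The changes between the days went alike in both genotypes. Of the genes called, 190 fell in both (6.46 expected by chance), 46 rose in both (1.14 expected by chance) and 0 went in opposite directions. Across genes, which are not independent replicates, the day differences of WT and KO had r = 0.814 and rho = 0.735. These differences share no array but are not independent. In each genotype array set 1 holds 1 array at day 6 and 3 at day 10, and array set 2 holds 2 at each day. Both differences thus carry part of the same difference between array sets. Calls in both genotypes also use the same variance per gene, which can raise their overlap above the chance values given. How much either adds was not tested. The differences between KO and WT at day 6 and at day 10 had r = 0.157 across genes and rho = 0.130.

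**Figure D3:**
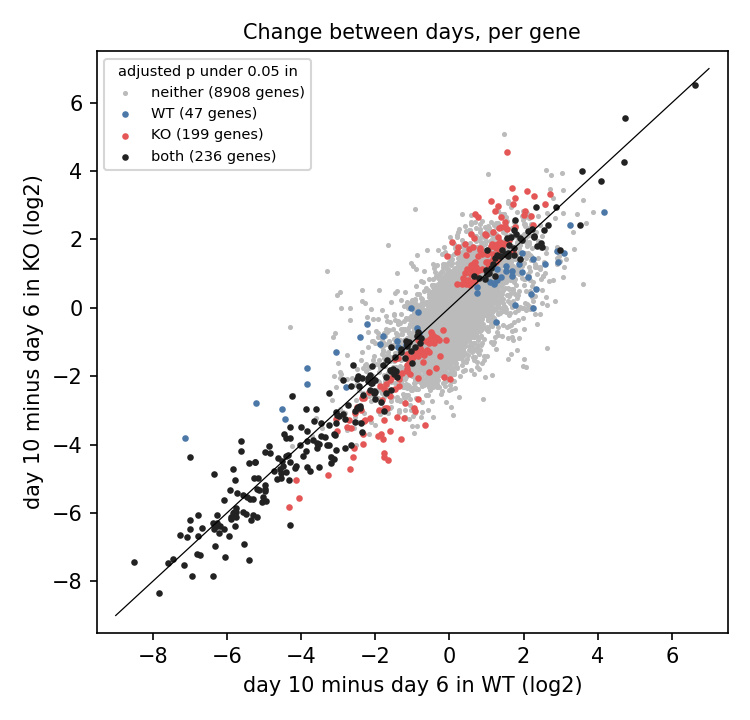
Log2 difference between day 10 and day 6 in WT (horizontal) and KO cells (vertical) for 9390 genes, coloured by where a gene was called; the black line marks equal differences. Genes called in both number 236, in WT alone 47, in KO alone 199 and in neither 8908.

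Markers of other cell types varied between arrays of the same group. Csf1r, the receptor for colony stimulating factor 1 on myeloid cells, ran from 11.6 to 14.07 on array set 1 and from 5.21 to 11.68 on array set 2. The macrophage gene Adgre1 ran from 5.23 to 9.44 and from 2.2 to 2.24, and the plasma cell gene Jchain from 11.69 to 13.80 and from 3.25 to 10.22. For the myeloid gene C1qb the ranges overlapped more widely, 7.105 to 14.28 and 2.722 to 11.76. The 7.105 was that of KO day 10 replicate 1, and the other arrays of set 1 read 11.57 or higher. The beta-actin 3′ minus 5′ difference did not differ between KO and WT by more than the spread of arrays at day 6 (exact permutation p = 0.8, n = 3 and 3, smallest possible 0.1) or day 10 (exact permutation p = 0.651, n = 5 and 5), nor did the share of probe sets over log2 4 (exact permutation p = 0.9 and 0.183).

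**Figure D4:**
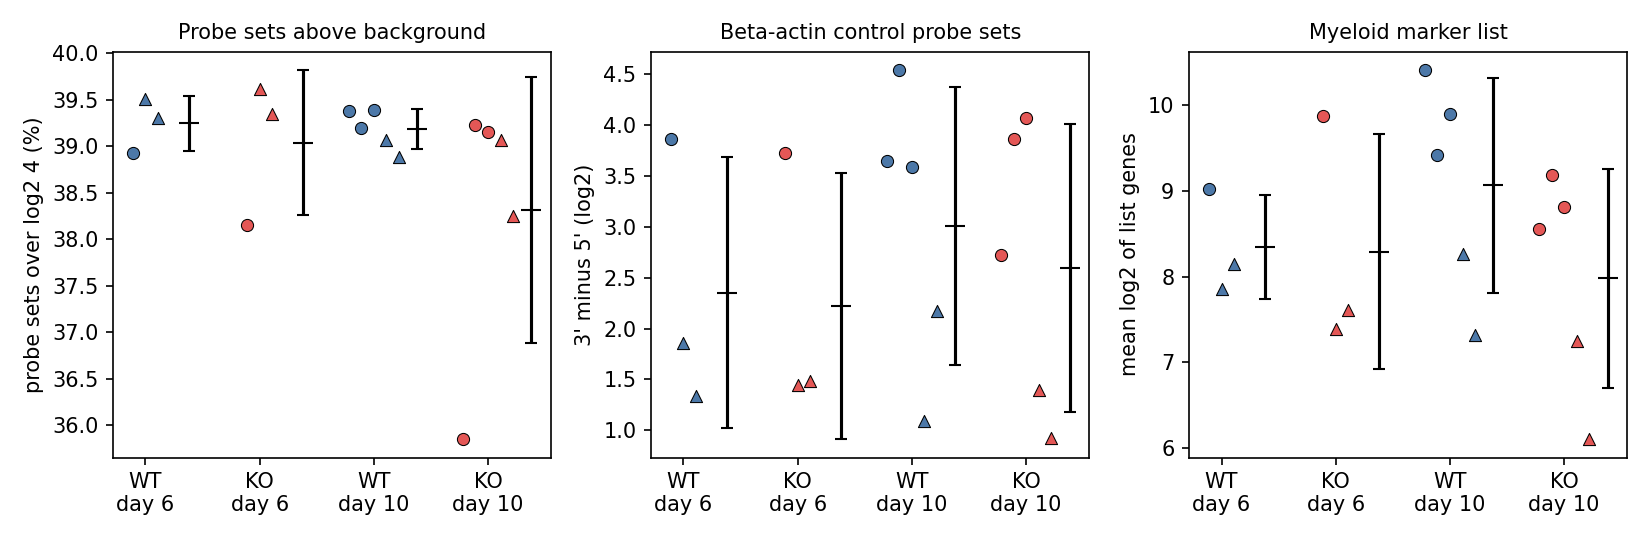
Quality and marker values of each array by group in 3 panels: percent of probe sets over log2 4, beta-actin 3′ minus 5′ difference in log2, and mean log2 value of the myeloid marker list. Circles are array set 1 and triangles array set 2, blue WT and red KO, and the black bar is the mean with its SD. KO day 10 replicate 1 lies lowest in the first panel at 35.85%.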

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

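All tests of the 3 patterns weighed in this part were chosen only after the results they measure were seen; the search for single arrays far from their group was set before.

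KO day 10 replicate 1 stood apart from the other 15 arrays. Its correlations with them over all genes were 0.854 to 0.9075, against 0.933 to 0.992 among the others, and 35.85% of its probe sets lay over log2 4, against 38.25% to 39.23% on the other KO arrays of day 10. Its beta-actin 3′ minus 5′ difference of 2.719 and Gapdh difference of 3.525 lay inside the ranges of the others (0.925 to 4.54 and 1.82 to 5.93). Both lay below every other array of array set 1, which read from 3.588 and 3.876 upward. By beta-actin and Gapdh, degraded RNA beyond that of those arrays is thus argued against. The ranges span both array sets, so they cannot exclude a lesser loss. The control probe sets for 18S ribosomal RNA read 12.91 (5′) and 13.15 (3′) on this array. The other arrays of set 1 read 3.383 to 7.642 and 4.327 to 7.571, and those of set 2 read 9.18 to 12.93 and 8.419 to 12.7. What the high 18S values on this array mean was not tested. A wrong label is argued against by Traf6 at 2.329. It is also argued against by 88% of the genes called between days in WT lying nearer to the WT mean of day 10 (other KO arrays 89% to 98.9% at day 10 and 5.3% to 11% at day 6). Single genes such as Kif11 and Prss12 nevertheless stood at their day 6 levels. Whether weaker transcripts were lost cannot be told apart from other causes: genes at log2 6 to 9 deviated by a median of -1.06 and genes over 12 by -0.16, a gap of -0.898 between the bounds set for a call. The design gives no biological explanation for 1 array of a group, and none was tested.

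On the same array list means were low in general, and 20 of the 27 list means were lowest there among the 5 KO arrays of day 10. Dixon's test was run on the fatty acid oxidation list and on lists past the threshold in a comparison, so the 3 lists it picked are no sign of a drop confined to metabolism: apoptosis genes averaged 8.804 (others 9.899 to 10.018) and autophagy and lysosome genes 9.108 (10.523 to 10.765). The fatty acid oxidation mean was 9.197 (others 10.83 to 11.08), the citric acid cycle mean 10.44 (11.43 to 11.68), the oxidative phosphorylation mean 11.23 (12.87 to 13.21) and Rad54b 2.331 (2.286 to 2.297, all at the floor). Of 132 groups of 5 arrays tested in this way 17 held an array beyond Dixon's limit of 0.71, 5 of them at this array. Chance gives about 1 in 20 for normally distributed values. Flagged genes such as Rad54b, E2f7 and Bub1b lay near the floor, where a very small shift exceeds the limit. The count is therefore not to be read as an excess over chance.

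Array sets 1 and 2, divided by the beta-actin difference, differed in 1317 of 9390 genes, 727 higher and 590 lower on set 1. KO day 10 replicate 1 was counted in set 1, with a beta-actin difference close to the dividing mean. On all other arrays the 18S ribosomal RNA controls were lower on set 1 than on set 2. Whether the gene differences follow that was not tested. Markers of myeloid cells (median 1.80), B cells (1.33), erythroid cells (1.43) and NK cells (1.67) were higher on set 1, as were interferon response (0.51) and cell cycle genes (0.25), while effector (-0.34) and oxidative phosphorylation genes (-0.31) were lower. A change of RNA integrity that acts alike on genes of like level is argued against, since the myeloid median exceeded 100% of the medians of 10000 random lists matched on level. A larger share of myeloid, B and erythroid cells on set 1 has the values it needs. The myeloid, B cell and erythroid medians each lay above 100% of their random lists. Csf1r and Jchain lay at 11.6 or higher on every array of set 1. The myeloid gene C1qb overlapped between the sets (7.105 to 14.28 on set 1 and 2.722 to 11.76 on set 2). Most of that overlap rests on KO day 10 replicate 1, at 7.105. The other arrays of set 1 read 11.57 to 14.28. The sort on CD45.2 was meant to remove such cells, so the larger share is a hypothesis. Platelet markers (2 genes, median 0.15) and CD4 and regulatory T cell markers (3 genes, median -0.50) lay within their random lists (above 44.91% and 12.84% of them) and are too few to tell for these cells, and, as the sets are not groups of the design, no biological explanation was tested.

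Xist, expressed from the inactive X chromosome of females, read 10.23 to 12.53 on 3 probe sets in WT day 6 replicates 2 and 3 and WT day 10 replicates 4 and 5, the WT arrays of set 2, and 2.14 to 2.32 on the other 12 arrays. Cross-hybridisation of 1 probe set is argued against by the lowest of these readings, 10.23, and lack of TRAF6 in the others by the highest value on the WT arrays of set 1, 2.144. A mixture of male and female cells on these 4 arrays has the values it needs: the Y-linked Kdm5d differed by -0.855 between WT and KO on set 2 (10.17 to 11.04 against 11.21 to 11.77, exact permutation p = 0.0286, n = 4 and 4, the smallest possible), and by 0.043 on set 1 (exact permutation p = 0.886). The Y-linked Eif2s3y stayed at 12.44 to 12.82 on these arrays and at 12.5 to 13.29 on the others. Whether female cells came from donors or from recipients is open, as is a difference of sex between the mice, and genotype and this difference overlap on set 2.

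Single arrays of day 10 lay beyond Dixon's limit for further named genes. Many of these readings lie under log2 4, near the floor, where a very small shift exceeds the limit. Ikzf2 read 5.563 in WT replicate 4 (other WT arrays 2.25 to 3.11). Cdc6 read 2.226 in WT replicate 4 (3.06 to 3.07). Traf6 read 2.873 in KO replicate 3 (other KO arrays 2.17 to 2.33). Slc15a2 read 12.34 in WT replicate 1 (12.94 to 13.18). In KO replicate 4 Trim17 read 2.182 (3.21 to 3.42) and E2f7 2.396 (2.23 to 2.24). In WT replicate 2 Rad54b read 2.791 (2.29 to 2.31) and Cdkn3 5.163 (2.27 to 2.39). In WT replicate 3 Bub1b read 3.12 (2.505 to 2.509) and Esco2 5.327 (2.40 to 2.87). Klk13 read 8.7 in WT replicate 5 (4.88 to 5.48), and Mcm10 5.93 in KO replicate 2 (2.55 to 3.33). A Traf6 probe set not used in the comparisons read 5.269 in KO day 10 replicate 5, above the highest WT value of 5.085.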

How the results depend on the processing

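Alternatives chosen only after the data were seen were those with an array set, the host marker covariate (the mean of B cell, myeloid and erythroid list genes), the beta-actin covariate, combinations with KO day 10 replicate 1 left out, and the genotype difference over both days; the others were planned. Where an alternative changed a result the cause was not tested, except that a stricter threshold calls fewer genes by construction. Traf6 kept its direction under every alternative in which it was tested at its own probe set, and passed in all of these except the fit of only the day 6 groups and array set 1 at day 6. Signal over background limits genes near the floor of the arrays, where a fold is bounded. Array sets 1 and 2 hold 1 and 2 arrays of each group at day 6, and an array alone in its group is assumed to vary like the others. For named genes 28 results reversed, 146 passed newly, 232 no longer passed and 4939 stayed as they were; for lists 31 reversed, 48 passed newly, 104 no longer passed and 840 stayed; for counts of the genotype difference over both days 2 moved and 1 stayed. For a list that reversed, the value given is its median difference, while the reversal is that of the test's direction.

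Set tests. With an estimated correlation 0 lists passed for KO minus WT at day 6, 0 at day 10, 1 between days in WT (cell cycle) and 1 in KO (cell cycle). With fry 0, 0, 2 and 7 passed for the genotype differences and the days in WT and KO (in KO with memory and naive genes and CD4 and regulatory T cell markers, which did not pass with camera), and the direction of fatty acid oxidation (-0.0114) and the TRAF6 pathway (-0.0045) at day 6 and of effector genes between days in WT (0.058) reversed.

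Filters and scaling. Without a filter 3 genes and 4 lists passed at day 6, 6 lists at day 10, 9 lists between days in WT and 2 genes in the interaction, and fatty acid oxidation (0.0039) and the TRAF6 pathway (0.0211) at day 6 reversed. With log2 over 6 required, 2 lists passed in the interaction. After quantile normalization 2 genes passed at day 6 (Traf6 and Ticrr), and 2 genes (Traf6 and Tmod4) and 6 lists at day 10, and the day 6 difference of the fatty acid oxidation mean became 0.00735 (exact permutation p = 1). With centring it became 0.0435 (exact permutation p = 0.7). The percent of called genes that were lower between days in WT was 73.9 with deposited values, 69.3 after quantile normalization and 79.8 after centring, and in KO 66.7, 57.4 and 63.6; between genotypes at either day it was 100 and, after quantile normalization, 50.

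Models. Array weights called 5 genes at day 6, 4 at day 10, 2311 and 737 between days in WT and KO and 1 in the interaction, with Rnf31 at day 6 (0.0925) and Hsp90aa1 at day 10 (-0.02962) reversed. A fit of only the 2 groups compared called 0 genes at day 6 (limma, 114 at an unadjusted p under 0.05), 615 between days in WT and 143 in KO. The replicate block called 2 genes at day 6, 5 lists at day 10, 103 genes and 8 lists between days in WT and 121 genes in KO, with effector genes in KO (-0.241) reversed.

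Probe sets and thresholds. With the mean of a gene's probe sets 0 genes passed at day 6 and 0 at day 10 (78 and 237 at an unadjusted p under 0.05). Reversed were Hadhb (-0.39), Acaa2 (0.20), Tox (-0.05025) and Cyld (0.12) at day 6, Btg2 (-0.0821) and Hsp90aa1 (-0.06915) at day 10, Sesn3 (-0.026) between days in WT, and Mtor (-0.48) and Smad3 (-0.13) in KO. Without probe sets marked as shared or cross-hybridising, Hsp90aa1 at day 10 (-0.27) and Cox5b (1.08) and Idh2 (0.63) between days in WT reversed. Counting every probe set gave 2 at day 6 and 1 in the interaction. An adjusted p under 0.01 left 167 genes between days in WT and 215 in KO.

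Leaving out 1 array at a time gave 1 to 3 genes and 0 to 2 lists at day 6, 1 to 3 genes and 0 to 5 lists at day 10, 187 to 540 genes and 3 to 6 lists between days in WT, 288 to 621 genes and 2 to 9 lists in KO, and 0 to 2 genes and 0 to 5 lists in the interaction. The extremes were WT day 6 replicate 1 (187 genes) and KO day 10 replicate 1 (540 genes) in WT, KO day 6 replicate 1 (288 genes) and KO day 10 replicate 1 (621 genes, 2 lists) in KO, WT day 10 replicate 4 (5 lists in the interaction, and 5 at day 10 as without WT day 10 replicate 5 or KO day 10 replicate 1), WT day 6 replicate 3 (2 lists at day 6) and WT day 6 replicate 2 (3 lists in WT). Ranges with a reversal at day 6 were -0.01231 to 0.404 for Hadhb and -1.28 to 0.81 for Rnf31 (both turning without KO day 6 replicate 1), -0.131 to 0.39 for Tollip (KO day 6 replicate 2), -0.0648 to 0.0694 for the fatty acid oxidation list (WT day 6 replicate 3 and KO day 6 replicate 1), -0.0666 to 0.0792 for the TRAF6 pathway list (KO day 6 replicate 2) and -0.0785 to 0.0526 for the fatty acid oxidation mean (WT day 6 replicate 1, 0.0102, and KO day 6 replicate 2, 0.0526). The TRAF6 pathway list at day 10 ranged from -0.193 to -0.0932 (turning without WT day 10 replicate 4) and effector genes between days in WT from -0.0087 to 0.103 (WT day 6 replicate 3 and WT day 10 replicate 2). The fatty acid oxidation mean between days in WT ranged from -0.255 to -0.198 and had an exact permutation p of 0.0571 without WT day 10 replicate 4 or 5.

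Array sets. The array set as a block gave 5 lists at day 10, and effector genes between days in WT (0.124) reversed. With KO day 10 replicate 1 left out as well, 2 genes and 0 lists passed at day 6, 2 genes and 6 lists at day 10, 897 genes between days in WT, 1136 genes and 5 lists in KO and 2 lists in the interaction; fatty acid oxidation at day 10 (0.0037) and effector genes in WT (0.111) reversed. On array set 1 alone 0 genes (545 at an unadjusted p under 0.05) and 2 lists passed at day 6, 2 genes and 4 lists at day 10, 3 lists between days in WT, 871 genes and 5 lists in KO and 1 list in the interaction. Reversed were the TRAF6 pathway at day 6 (-0.0635), glycolysis in WT (0.0739), effector genes in KO (-0.151) and Recql4 in the interaction (-0.34). On array set 2 alone 6 genes and 0 lists passed at day 6, 3 genes at day 10, 3 lists between days in WT, 5 in KO and 2 in the interaction. Xist had the smallest p of these genes on both days (-10.13 at day 6 and -10.17 at day 10). The gene counts thus include the Xist difference, which overlaps with genotype on set 2. Reversed were Rnf31 at day 6 (0.42), Gzmk (0.14), Acaa2 (0.03531), Btg2 (-0.13) and fatty acid oxidation (-0.0559) at day 10, effector genes in WT (0.189), and Fosl2 (-0.07955), Mtor (-0.19) and the PI3K and mTOR list (-0.121) in KO. The count between days in WT was 348 with the block (277 of them among the 283), and 94 and 156 of the 283 were called on array sets 1 and 2. In KO it was 605 with the block (426 among the 435), with 192 and 194 called on the sets.

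Replicate block and covariates. The replicate block without KO day 10 replicate 1 gave 4 genes and 0 lists at day 6, 5 lists at day 10, 9 lists between days in WT, 207 genes in KO and 2 lists in the interaction, with fatty acid oxidation at day 10 (-0.0276), Ski (-0.001015), effector genes (0.104) and the PI3K and mTOR list (0.0524) in KO reversed. With the host marker covariate, which holds the myeloid genes themselves and so tests nothing about them, the myeloid list at day 10 (-0.163) and effector genes in WT (0.134) reversed. With KO day 10 replicate 1 left out as well it gave 2 genes and 0 lists at day 6, 2 genes and 1 list at day 10, 663 genes between days in WT and 815 genes and 4 lists in KO, and reversed Btg2 (-0.01469), Rtp4 (0.092), Myd88 (0.0417) and fatty acid oxidation (0.0195) at day 10 and effector genes in WT (0.124). The beta-actin covariate gave 0 lists at day 10 and reversed effector genes in WT (0.121). Without KO day 10 replicate 1 it gave 2 genes and 0 lists at day 6, 2 genes and 4 lists at day 10, 924 genes in WT, 1163 genes and 5 lists in KO and 2 lists in the interaction, and reversed fatty acid oxidation at day 10 (-0.0111) and effector genes in WT (0.116).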

Other observations

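The tests of splits of the samples in this part were planned; the genotype difference over both days, and the lists described first, were chosen only after the data were seen.

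Genes of 2 receptors of the TNF family moved in opposite directions between the days in both genotypes. Tnfrsf9, which encodes the costimulatory receptor 4-1BB induced on activated T cells, fell by 2.003 in WT (SE 0.39, n = 3 and 5, limma adjusted p = 0.0092) and fell by 2.11 in KO cells (adjusted p = 0.0052). Tnfrsf4, which encodes OX40, rose by 1.77 in WT (SE 0.44, adjusted p = 0.044) and by 2.58 in KO (adjusted p = 0.0028). For both genes the arrays of the 2 days did not overlap in either genotype. This held for 20.5% of the 9390 tested genes in WT and 12.7% in KO, so it does not set these genes apart. The direction was kept under each of 27 alternatives. Without overlap, leaving out an array cannot turn the direction, so the kept direction adds little. Tnfrsf9 passed in 22 of these in WT (adjusted p up to 0.173; not past without WT day 6 replicate 1) and 23 in KO (up to 0.133). Tnfrsf4 passed in 25 in KO (up to 0.0688) but in 13 in WT (up to 0.281), where it failed without any 1 of the WT arrays except WT day 10 replicate 4. They were the only called members of the 21 NF-kB target genes in each genotype, 1 up and 1 down, and the counts were the same when adjusted over the list alone. The list itself did not pass (median 0.31 in WT and 0.16 in KO, camera adjusted p = 0.592 and 0.670, with fry 0.610 and 0.764). Ier3 stood at 0.74 and Icam1 at 0.58 in WT, and Tnfaip8 at -0.66 and Irf1 at 0.47 in KO.

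Pik3ip1, an inhibitor of PI3K in T cells, rose by 0.97 in WT (SE 0.19, adjusted p = 0.0089) and by 0.84 in KO cells (SE 0.19, adjusted p = 0.018). The arrays of the 2 days did not overlap in either genotype, as for 20.5% of tested genes in WT and 12.7% in KO. The direction was kept under 27 alternatives, which adds little where arrays do not overlap. Of these alternatives 20 in WT and 19 in KO passed (adjusted p up to 0.781 and 0.469, both with the mean of probe sets). Leaving out single arrays ended the call: WT day 6 replicate 1 in WT, and KO day 6 replicate 1 (0.0661) or 3 (0.0607) in KO. It was the only called member of the 21 genes of the PI3K and mTOR list, over all genes and adjusted over the list alone, and the list did not pass (median 0.32 in WT and 0.30 in KO, adjusted p = 0.226 and 0.103). The list passed in KO without KO day 6 replicate 2 (adjusted p = 0.033) and on array set 1 alone (adjusted p = 0.0279), against up to 0.925 over 31 alternatives, 2 of them with the opposite direction. Sesn3 at 0.67 in WT, Mtor at 0.78 and 0.67, Foxo3 at 0.61 and 0.89 in WT and KO, and Rheb at -0.41 in KO did not pass, and without KO day 6 replicate 1 Foxo3 was at 0.43, Mtor at 0.34 and Rheb at -0.25 in KO. The interaction had an adjusted p of 0.999 for each of the genes named here.

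Averaged over both days, the difference between KO and WT was called for 1 gene, Traf6. Slc15a2 came next at -1.95 (SE 0.31, adjusted p = 0.080), then Tmod4 at 2.51 (SE 0.47, adjusted p = 0.308), Eps8l1 at -2.08 and Ikzf2 at 2.39 (adjusted p = 0.994 for both). Without KO day 10 replicate 1 the count was 3, with Slc15a2 at -2.13 (adjusted p = 8.4e-04) and Cyp17a1, a steroid hydroxylase gene, at -1.96 (adjusted p = 0.025). With the array set as a block and all arrays it was 1 (Slc15a2 0.151), and with that block and the array left out 3 (Slc15a2 0.0015, Cyp17a1 0.04999).

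Other splits of the same arrays tested whether a grouping by chance gives as much. Between the days chance can be excluded for the genes called in WT (1 of 56 splits, the real one with 283 genes, highest other 13) and in KO (1 of 56, 435 genes, highest other 16). For the lists in KO the share lay under 0.05 (2 of 56, 8 lists). Another split gave as many lists (highest other 8), so chance is not excluded there. That other split set KO day 10 replicates 1, 2 and 5 against the rest, and the count of 8 dropped to 2 without KO day 10 replicate 1 and to 1 with an estimated correlation. Chance cannot be excluded for the lists in WT (15 of 56, 5 lists, highest other 9). At day 10 it cannot be excluded for the lists (59 of 100, 2 lists, highest other 6) or, by count, for the genes (6 of 100 splits, 1 gene, highest other 112). That 1 gene is Traf6, the deleted gene, which did not overlap between the genotypes (adjusted p = 1.9e-07), so the count says nothing against it. The split with 112 genes set WT replicates 1 to 3 and KO replicates 2 and 3 against the rest, that is 5 of the 6 arrays of set 1 against those of set 2 with KO replicate 1, the array that stands apart. It thus followed the array sets except for that array, which points to a structure of the samples, and with the array set as a block the real split called 1 gene. At day 6 the splits are too few for a share under 0.05, with 7 of 10 as large for genes (real 1, highest other 7) and 2 of 10 for lists (real 1, highest other 1). Of these 10 splits 4 parted all 3 pairs of like number, as the real one does, and the 3 others among them called 0 to 1 genes, while the 6 that parted 1 pair called 0 to 7. For the interaction the real counts were 0 (limma, 84 genes at an unadjusted p under 0.05), so 100 of 100 splits were as large by construction (highest other 3 genes and 5 lists) and nothing about chance follows.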
